A study of Mus musculus with 24 samples.

How the data were processed

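RNA was measured in 24 mouse samples of peritoneal metastasis, 6 in each of 4 groups: control, propionate, butyrate and a combination of both acids. Per the labels' protocols, RNA was extracted with TRIzol and sequenced as stranded libraries of polyadenylated RNA. The submitters' processing notes name fastp, a read trimmer, HISAT2, an aligner, StringTie, which assembles and quantifies transcripts, and the mouse build mm39. Their versions, settings and order and the gene annotation are not given in the sources used here.

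The authors deposited a single table of TPM, transcript abundance scaled to a fixed total per library, with 149132 transcripts and 1 column per library. Each deposited TPM column summed to 1000000 over all transcripts, so a transcript that takes a larger share lowers the TPM of the others. TPM keeps no sequencing depth, so the depth of these libraries is unknown and no counting interval could be given. Transcripts without a gene name numbered 1001 and held 0.174 to 0.470% of the TPM of a library, and 42729 transcripts were at 0 in all libraries. TPM was summed over the transcripts of each gene name, which gave 56422 names, of which 21133 had several transcripts. Transcripts without a gene name were left out of the tests.

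Genes with a TPM of at least 1 in at least 6 libraries were tested, 15163 in all. Of these names, 14458 (95.4%) matched a symbol in a mouse reference annotation of an older build, which was used for no other purpose, so no coordinates are given. Stranded libraries keep a gene and its antisense partner apart only if the counting used the strand, which is not stated. Pseudogenes and members of multigene families are uncertain where reads could be shared between copies.

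Values were analysed as log2(TPM + 1), with a pseudocount of 1, so log2 fold changes understate the change of genes near 0. Linear models were fitted with limma 3.58.1 (empirical Bayes moderation with an intensity trend and robust settings) in R 4.3.3, with all 24 libraries in one fit. From this fit came 7 comparisons: each treated group against control, the combination against each acid alone, butyrate against propionate, and the interaction. The interaction was the difference of combination and propionate minus the difference of butyrate and control. Every gene p-value is two-sided, from limma's moderated test, with Benjamini-Hochberg adjustment over the 15163 genes of a comparison and a threshold of 0.05. Values after ± are SDs for TPM and list scores and SEs for log2 fold changes.

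Gene lists, 42 in number, covered targets of short-chain fatty acids, immune cell types and responses, tumour programmes, metabolism and other tissues that a sampled piece could hold. They were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and with adjustment over the 42 lists of a comparison. Each list was also tested by camera with an estimated correlation and by fry, which asks whether the genes of a list move one way on balance. Within a list, the number of genes passing was counted when adjusted over the list alone and over all genes. Counts of the genes of a list are of tested members, and members below the filter are left out. A list score, the mean log2(TPM + 1) of its tested members, was compared between groups by a two-sided exact permutation test over 924 arrangements, which cannot give a p below 0.00216. For the 3 comparisons with control these permutation tests were adjusted in a family of 39 planned measures of tissue make-up and in a family of 126 for all lists.

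The groups, the comparisons, the tests, the gene lists and the rule for naming genes were set before the data were examined. By that rule, genes past the threshold would be named by the size of their change. Where fewer than 10 passed, the 10 genes of smallest unadjusted p with a mean log2(TPM + 1) of at least 1 are named and said not to have passed. A result that this rule would name is not reported here. Up to 4 members of smallest p were named for a described list, and 13 genes were always reported: Ffar2, Ffar3, Hcar2, Slc16a1, Cd8a, Gzmb, Prf1, Ifng, Pdcd1, Cd274, Foxp3, Mki67 and Cdkn1a.

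Other settings tried were a pseudocount of 0.1, no filter on low values, a filter of TPM at least 5, median-of-ratios scaling, quantile normalization and weights estimated per library. Others were a fit of only the compared groups, moderation without trend and robustness, a block by the replicate number of the title or of the library description, and leaving out each library in turn. A further fit took the first 2 principal components of the scores of 8 lists of other tissues as covariates, called the tissue covariates below. The 8 were adipocyte, skeletal muscle, smooth muscle, exocrine pancreas, hepatocyte, intestinal epithelium, ovary and erythroid genes. These covariates remove part of the differences of those 8 lists by construction. Ended or turned calls of these lists with the tissue covariates thus test nothing. Fits without combination replicate 5, alone or with tissue covariates, were added after seeing the data. Splits of the samples into other groups were refitted in 100 draws, the real split included.

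The limma step was tested on simulated data for the comparison of propionate with control, with 200 of 15163 genes changed. With independent noise, 42.5, 92 and 98.5% of genes changed by log2 1, 2 and 3 were recovered, with 6, 17 and 10 false calls. With residuals of whole libraries as noise, 37.5, 84 and 97.5% were recovered, with 0, 0 and 2 false calls. In the simulated list test, run with independent noise only, camera called 1 list, the one that had been raised by log2 1. Independent noise holds no correlation between genes, so that test cannot show whether such correlation brings false list calls. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.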

Results

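Transcript abundance was measured by RNA sequencing in 24 mouse samples of peritoneal metastasis, tumour growth on the lining of the abdominal cavity. The title of the series ties them to mannose, anti-PD-1 treatment of ovarian cancer and a gut microbial metabolite. Control, propionate, butyrate and combination groups held 6 samples each. Propionate and butyrate are short-chain fatty acids (SCFA) that gut bacteria make from fibre, and the carbon chain of butyrate is 1 carbon longer. The labels state no dose, time point, tumour line or anti-PD-1 treatment. They also do not state that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical.

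The libraries held 12618 to 15418 genes with a TPM of at least 1, and their 50 most abundant genes took 30.95 to 59.5% of the TPM. Transcripts encoded in the mitochondrial genome took 12.8 to 26.8%. Skeletal muscle markers were abundant in every group, with a mean list score of 11.1 ± 0.77 (SD, n = 6) in control, 11.4 ± 0.96 with propionate and 11.6 ± 0.26 with butyrate. Combination replicate 5 stood apart, with a skeletal muscle score of 1.28 and 67.3 TPM of the cytotoxic T cell gene Cd8a. Across all libraries, the first principal component of log2(TPM + 1) held 62.4% of the variance and the second 15%. Libraries with 131 TPM or more of Wt1, a gene of the mesothelium list, lay at -33.4 or below on the first component. They were control replicates 1, 2, 4, 5 and 6, propionate replicates 3 and 4, butyrate replicate 2 and combination replicates 3 and 4. Libraries with 28.0 TPM or less lay at 15.3 or above, except combination replicate 5 (0 TPM, -73.6). Krt8, of the list of epithelial and ovarian carcinoma genes, ran with Wt1. It was at 95.6 TPM or more in the libraries high in Wt1 and at 23.3 TPM or less in those low in it. Combination replicate 5 was again the exception (123 TPM). By these genes the first component does not tell mesothelium from tumour.

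Propionate against control asked what propionate alone did in the metastases. Proliferation genes were lower: all 20 tested members of the cell cycle list lay below control, with a mean log2 fold change of -1.39 (n = 6 per group). Mki67, a marker of cycling cells, averaged 4.70 ± 6.52 TPM (SD) against 11.2 ± 7.91 in control, a log2 fold change of -1.57 ± 0.71 (SE). The mitotic kinases Aurka and Aurkb were at -0.73 ± 0.28 and -1.52 ± 0.64, and Birc5, which encodes survivin, at -1.90 ± 0.81. Camera called the list lower (adjusted p = 0.000138), but adjusted p = 0.787 with an estimated correlation. Of the 20 members, 12 had an unadjusted p under 0.05, 0 passed in limma when adjusted over the list alone and 0 over all genes. Mesothelium markers moved the same way, with a score of 3.12 ± 1.63 against 4.42 ± 1.54, as did ovary markers at 2.10 ± 2.12 against 3.80 ± 1.69. The propionate libraries were split: replicates 3 and 4 held 14.98 and 10.88 TPM of Mki67 and scored 3.679 and 3.195 for epithelial and ovarian carcinoma genes, and the other 4 held 0.22 to 1.21 TPM and scored 0.673 to 1.5. The carcinoma score averaged 1.78 ± 1.32 against 2.91 ± 1.24 in control (exact permutation p = 0.197). With tissue covariates the mean of the cell cycle list was -0.29, and camera still called it lower.

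Genes of energy metabolism and fat were called higher with propionate, relative to a median log2 fold change of -0.30 over all 15163 genes. All 11 mitochondrially encoded genes were above control, with a mean of 0.30, and mt-Atp6, a subunit of ATP synthase, at 0.48 ± 0.22 (SE, n = 6 per group). All 14 adipocyte genes were above control, with a mean of 0.47. Among them Pck1, a gluconeogenic enzyme active in fat, was at 1.09 ± 0.64 and Adipoq, which encodes adiponectin, at 0.61 ± 0.55. Of 20 oxidative phosphorylation genes, 18 were above control, at a mean of 0.08. Camera called these lists higher (adjusted p = 7.26e-11, 2.70e-09 and 2.37e-08), but each had adjusted p = 0.522 with an estimated correlation. Median-of-ratios scaling moved the median of all genes to -0.003 and quantile normalization to 0.04. The former gave means of 0.665, 0.80 and 0.44 for the mitochondrially encoded, adipocyte and oxidative phosphorylation lists, and the latter 0.76 and 0.26 for the last 2 and ended the mitochondrially encoded call at 0.10. With tissue covariates the adipocyte call ended at -0.07 and that of oxidative phosphorylation turned to lower at -0.105. Its mean was -0.001, 0.16, 0.14 and 0.05 without propionate replicates 2, 3, 4 and 5, and 0.02, 0.15 and 0.05 without control replicates 2, 3 and 5.

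Of the skeletal muscle genes, 15 of 16 were above control with propionate, with a mean of 0.31, and camera called the list higher (adjusted p = 8.89e-05, but adjusted p = 0.750 with an estimated correlation). Median-of-ratios scaling, quantile normalization and tissue covariates each ended the call, at 0.67, 0.17 and -0.03, and weights per library gave 0.76. The mean was 0.04 and 0.47 without control replicates 2 and 3, and 0.19, 0.13, 0.62, 0.47 and 0.196 without propionate replicates 1, 2, 3, 4 and 5, still called in each.

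Camera called 14 of 42 lists with propionate, 13 higher and 1 lower, and 0 with an estimated correlation (3 at unadjusted p under 0.05) or by fry. No gene passed in limma: 0 of 15163 had an adjusted p under 0.05, 66 were higher and 1385 lower at an unadjusted p under 0.05, and the smallest adjusted p was 0.333. The 10 named genes therefore did not pass. Il15, a cytokine that sustains natural killer and memory CD8 T cells, averaged 14.9 ± 2.64 TPM against 8.81 ± 2.96, a log2 fold change of 0.73 ± 0.19, and was higher in 33 of 36 pairs of libraries. Nr1d1, a repressor of the circadian clock, was at 0.63 ± 0.20. Below control were the stress-response transcription factor gene Jun at -0.71 ± 0.21 and Spry4, an inhibitor of receptor tyrosine kinase signalling, at -0.65 ± 0.20. Pdlim1 was at -0.64 ± 0.17, the RNA-binding protein gene Igf2bp2 at -0.80 ± 0.25, the uracil-DNA glycosylase gene Smug1 at -0.67 ± 0.22 and Vps37c at -0.66 ± 0.20. Agpat5 was at -0.31 ± 0.10, with 0 of 36 pairs higher, and Fam104a at -0.32 ± 0.10. With weights estimated per library, 11434 genes passed, 1431 higher and 10003 lower. The weights were 0.127 and 0.181 for propionate replicates 3 and 4 and 0.26 for control replicate 3, against 6.761 for propionate replicate 5. That fit thus leaned away from the propionate libraries with most Mki67 and the control library with least.

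Genes that handle short-chain fatty acids gave small values with propionate. Ffar2, a receptor for these acids, averaged 0.66 ± 0.27 TPM against 0.73 ± 0.30, and its log2 fold change of -0.06 was 0.05 with median-of-ratios scaling. Hcar2, a receptor for butyrate and ketone bodies, was at 0.19 ± 0.29. Slc16a1, a carrier of monocarboxylates, averaged 15.5 ± 4.68 TPM against 21.9 ± 4.07, a log2 fold change of -0.50 ± 0.21 (limma, adjusted p = 0.333). The list of 19 genes of SCFA and ketone body catabolism had a mean of 0.06 and was called higher (adjusted p = 0.000298, but adjusted p = 0.522 with an estimated correlation). Its mean was 0.03 without control replicate 1 or propionate replicate 2, 0.09 without control replicate 3, and with tissue covariates the call ended at -0.035.

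Butyrate against control asked the same of butyrate alone. Cell cycle genes were lower again: all 20 lay below control, with a mean log2 fold change of -1.56 against a median of -0.38 over all genes (n = 6 per group). The replication genes Mcm2, Rrm2 and Pcna were at -1.56 ± 0.58, -1.73 ± 0.67 and -1.47 ± 0.59 (SE), Aurka at -0.86 ± 0.28, and Mki67 averaged 2.80 ± 2.79 TPM against 11.2 ± 7.91. Of the 20 genes, 18 fell when adjusted over the list alone and 0 over all genes. Camera called the list lower (adjusted p = 0.00781), but adjusted p = 0.968 with an estimated correlation. Its score was 2.18 ± 0.94 against 3.74 ± 1.20 in control, with an exact permutation p = 0.0368 (adjusted p = 0.364 over 126 tests, 4 of 36 pairs higher). Mesothelium, ovary and exocrine pancreas scores moved with it, at 2.88 ± 1.01, 1.85 ± 1.37 and 1.26 ± 0.87 against 4.42 ± 1.54, 3.80 ± 1.69 and 2.83 ± 1.23. With tissue covariates the mean was -0.24 and the call ended.

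Mitochondrially encoded genes were higher with butyrate: all 11 lay above control, with a mean of 0.51. The complex I subunit mt-Nd3 was at 0.93 ± 0.28 (SE, n = 6 per group), mt-Co3 of cytochrome oxidase at 0.73 ± 0.27, mt-Atp6 at 0.71 ± 0.22 and mt-Nd6 at 0.40 ± 0.15. Of these genes, 9 rose when adjusted over the list alone and 0 over all genes. Camera called the list higher (adjusted p = 1.29e-14), but adjusted p = 0.370 with an estimated correlation. All transcripts encoded in the mitochondrial genome, a wider set than this list, took 23.2 ± 2.47% of the TPM against 16.6 ± 3.72% in control, and the 50 most abundant genes 53.3 ± 4.95 against 40.6 ± 7.97% (exact permutation p = 0.0108 for both, adjusted p = 0.141). Adipocyte genes, all 14 above control with a mean of 0.56, and skeletal muscle genes, all 16 above control with a mean of 0.54, were also called higher. Their adjusted p values were 2.01e-08 and 2.32e-05, with adjusted p = 0.640 and 0.772 with an estimated correlation. Quantile normalization ended the mitochondrially encoded and muscle calls at 0.20 and 0.45, median-of-ratios scaling the muscle call at 0.98, and tissue covariates the adipocyte and muscle calls at -0.03 and -0.01. The mitochondrially encoded and adipocyte means were 0.955 and 0.97 with median-of-ratios scaling, and the latter 0.96 with quantile normalization. Without control replicate 2 the muscle mean was 0.27.

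Across all lists, camera called 9 higher and 1 lower with butyrate, and 0 with an estimated correlation (1 at unadjusted p under 0.05) or by fry. In limma 0 of 15163 genes passed, while 181 were higher and 5325 lower at an unadjusted p under 0.05, with a smallest adjusted p of 0.115. The median log2 fold change of all genes, -0.38, was -0.014 with median-of-ratios scaling and 0.03 with quantile normalization. Vps37c, a subunit of the endosomal sorting complex ESCRT-I, averaged 12.4 ± 2.19 TPM against 24.6 ± 5.85, a log2 fold change of -0.91 ± 0.20 with 0 of 36 pairs higher. Among the other named genes, none past the threshold, Mtrr, which regenerates methionine synthase, and Fdx1, the mitochondrial ferredoxin of steroid synthesis, were both at -0.52 ± 0.12. Timm50, of the mitochondrial import machinery, was at -0.52 ± 0.12 and Oxnad1 at -0.80 ± 0.19. The splicing factor gene Sf3a2 was at -0.85 ± 0.20, the heat shock regulator Hsf1 at -0.62 ± 0.15, Btbd2 at -0.69 ± 0.16 and Ppp1r37 at -0.62 ± 0.14. Slc16a1 averaged 12.3 ± 1.84 TPM against 21.9 ± 4.07, at -0.78 ± 0.21 (limma, adjusted p = 0.115). Ffar2 was at 0.07 ± 0.36 and Hcar2 at 0.23 ± 0.29. Weights estimated per library gave 10256 genes, 958 higher and 9298 lower, a block by library number 7903, and leaving out control replicate 3 gave 5654, 162 higher and 5492 lower.

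Combination against control asked what both acids did together. Neutrophil genes were higher: all 8 tested members lay above control, with a mean log2 fold change of 1.145 against a median of -0.12 over all genes (n = 6 per group). Retnlg was at 1.29 ± 0.30 (SE), the decoy interleukin-1 receptor gene Il1r2 at 0.98 ± 0.26, the collagenase gene Mmp9 at 1.09 ± 0.30 and the alarmin gene S100a9 at 1.97 ± 0.58. Of the 8 genes, 5 rose when adjusted over the list alone and 0 over all genes. Camera called the list higher (adjusted p = 3.05e-09), with adjusted p = 0.0328 with an estimated correlation, the 1 list that kept its call there, and fry gave an adjusted p of 0.00851. Its score was 3.12 ± 0.67 against 1.97 ± 0.44, higher in 35 of 36 pairs, with an exact permutation p = 0.00433 (adjusted p = 0.273 over 126 tests). Without combination replicate 5 the mean was 0.946, and the list was called in each of the 12 fits without 1 library.

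T cell and cytotoxic genes were higher in the combination group. All 16 T cell genes lay above control, with a mean of 1.20, among them Cd247 and Cd3e of the T cell receptor complex at 1.67 ± 0.44 and 1.53 ± 0.59 (SE, n = 6 per group). The co-stimulatory receptor gene Cd28 was at 0.84 ± 0.30 and the adhesion receptor gene Cd2 at 1.39 ± 0.51. All 8 tested cytotoxic effector genes lay above control, with a mean of 1.34. They included the granzyme genes Gzmb and Gzma at 1.12 ± 0.27 and 1.49 ± 0.37, the receptor gene Klrk1 at 1.28 ± 0.45 and Nkg7 at 1.65 ± 0.59. Gzmb was at 0.79 TPM or less in every control library. Other members of that list, Prf1 and Ifng among them, were below the filter and not tested. When adjusted over the list alone, 1 T cell gene and 5 cytotoxic genes rose, and 0 over all genes. Camera called both lists higher (adjusted p = 6.30e-11 and 5.67e-09), but adjusted p = 0.377 and 0.249 with an estimated correlation. The cytotoxic score was 2.84 ± 1.39 against 1.497 ± 0.43 (exact permutation p = 0.0368, adjusted p = 0.364 over 126 tests, 30 of 36 pairs higher). Without combination replicate 5 the means were 0.505 and 0.93, with weights per library 0.30 and 0.80, and both lists were still called.

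**Figure D1:**
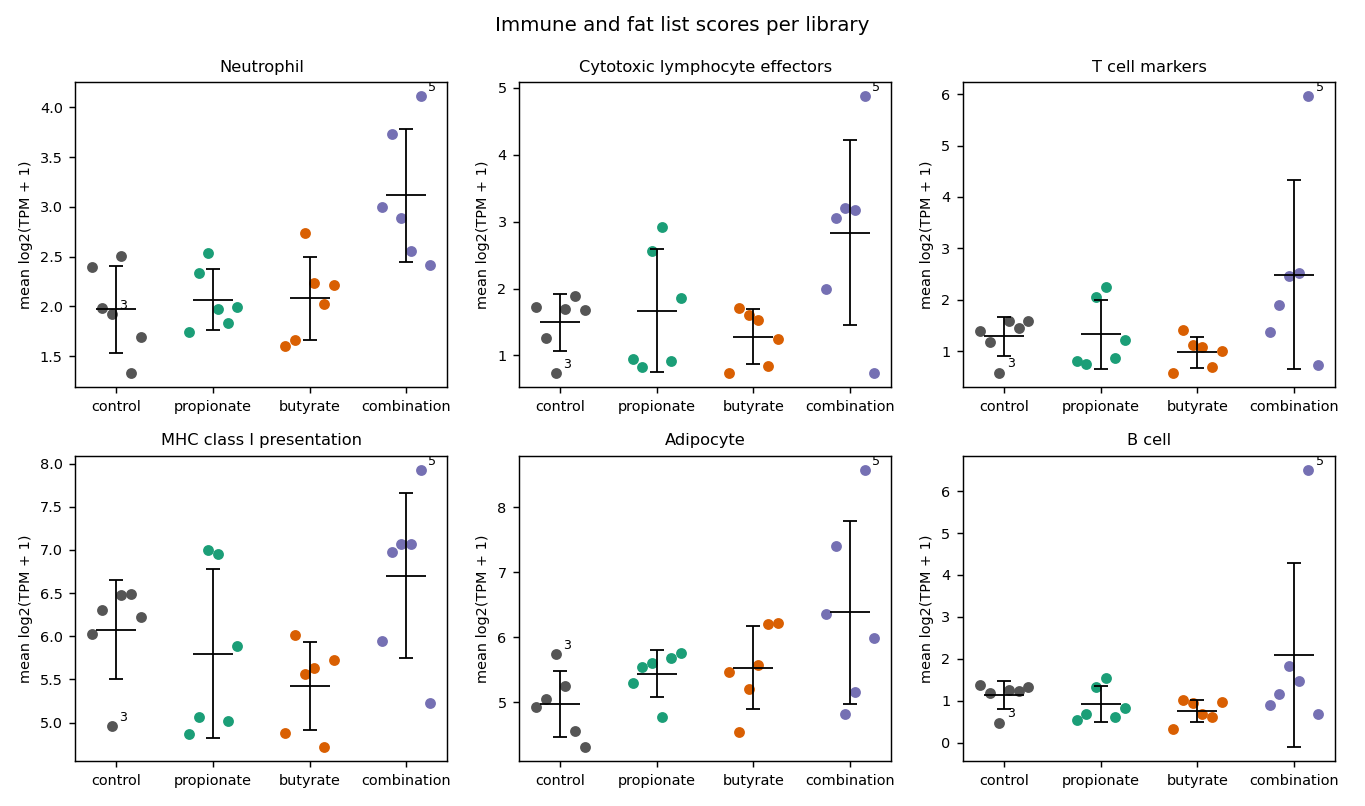
Immune and fat list scores by group. Points are libraries (6 per group) on an axis of mean log2(TPM + 1) over the members of a list, bars give the mean and SD, 5 marks combination replicate 5 and 3 marks control replicate 3; the neutrophil score averaged 3.12 in the combination group and 1.97 in control.

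Interferon and antigen presentation genes were called higher in the combination group. All 16 interferon gamma response genes lay above control, with a mean of 0.60, among them the GTPase genes Gbp5 at 1.06 ± 0.32, Gbp7 at 0.87 ± 0.33, Tgtp1 at 1.06 ± 0.42 and Iigp1 at 1.26 ± 0.57 (SE, n = 6 per group). Of 18 type I interferon response genes, 15 lay above control, with a mean of 0.39, and the antiviral gene Rsad2 at 0.93 ± 0.24. In the class I presentation list, 13 of 14 lay above control, with a mean of 0.63, H2-Q4 at 0.91 ± 0.38 and H2-D1 at 0.73 ± 0.36. Camera gave each list an adjusted p of 8.00e-06, but adjusted p = 0.532 with an estimated correlation. Adjusted over the list alone, 1 gene rose (Rsad2), and 0 over all genes. Means moved without single libraries: type I interferon to 0.24 and class I to 0.38 without combination replicate 5, interferon gamma to 0.37 and class I to 0.40 without control replicate 3, and interferon gamma to 0.90 without combination replicate 6.

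Macrophage genes of the peritoneal and alternatively activated kinds gave mixed values. Of 9 genes of alternative activation, 6 lay above control, with a mean of 0.42. The resistin-like gene Retnla was at 1.72 ± 0.47 (SE, n = 6 per group), the lectin genes Clec10a and Mgl2 at 0.70 ± 0.20 and 0.75 ± 0.22, and the eosinophil chemokine gene Ccl24 at 1.22 ± 0.36. These 4 rose when adjusted over the list alone. Of 8 resident peritoneal macrophage genes, 5 lay above control, with a mean of 0.33; Icam2 was at 0.95 ± 0.28, Timd4 at 1.68 ± 0.50, Cd209b at 1.64 ± 0.64 and F10 at 0.61 ± 0.26, and 3 genes rose when adjusted over the list alone. None of either list passed over all genes (0). Camera called both higher (adjusted p = 0.000260 and 0.00872), but adjusted p = 0.249 for both with an estimated correlation. The mean of alternative activation was 0.26 without control replicate 3 (0.263) or combination replicate 3 (0.255). That of resident macrophages was 0.18 without control replicate 3, 0.115 without combination replicate 5 and 0.51 without combination replicate 6, and quantile normalization ended its call.

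Tissue markers differed in the same comparison. All 14 adipocyte genes lay above control, with a mean of 1.41, and 12 rose when adjusted over the list alone, among them the fatty acid carrier gene Fabp4 at 1.69 ± 0.51 (SE, n = 6 per group), Pck1 at 2.10 ± 0.64, the fat cell regulator Pparg at 1.47 ± 0.46 and Adipoq at 1.75 ± 0.55. All 14 mesothelium genes lay below, with a mean of -1.43, including Msln, which encodes mesothelin, at -1.96 ± 0.95 and Upk1b at -1.88 ± 0.88. All 20 cell cycle genes lay below, with a mean of -0.97, and Aurka at -0.61 ± 0.28. Camera called these lists (adjusted p = 5.21e-14, 0.000808 and 0.000598), but adjusted p = 0.249, 0.545 and 0.623 with an estimated correlation. Skeletal muscle genes were called lower at a mean of -1.48 (adjusted p = 0.00924, but adjusted p = 0.648 with an estimated correlation). Without combination replicate 5 the muscle mean was 0.19 and was called higher, and without control replicate 3 the call ended at -1.31, as it did in a fit of the 2 groups alone or with a block by library number. With tissue covariates the adipocyte call ended at 0.25, and the means of mesothelium, cell cycle and skeletal muscle turned to 0.35, 0.17 and 0.08, with no call. The adipocyte and skeletal muscle lists helped to make those covariates, so for these lists the loss of the call tests nothing.

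**Figure D2:**
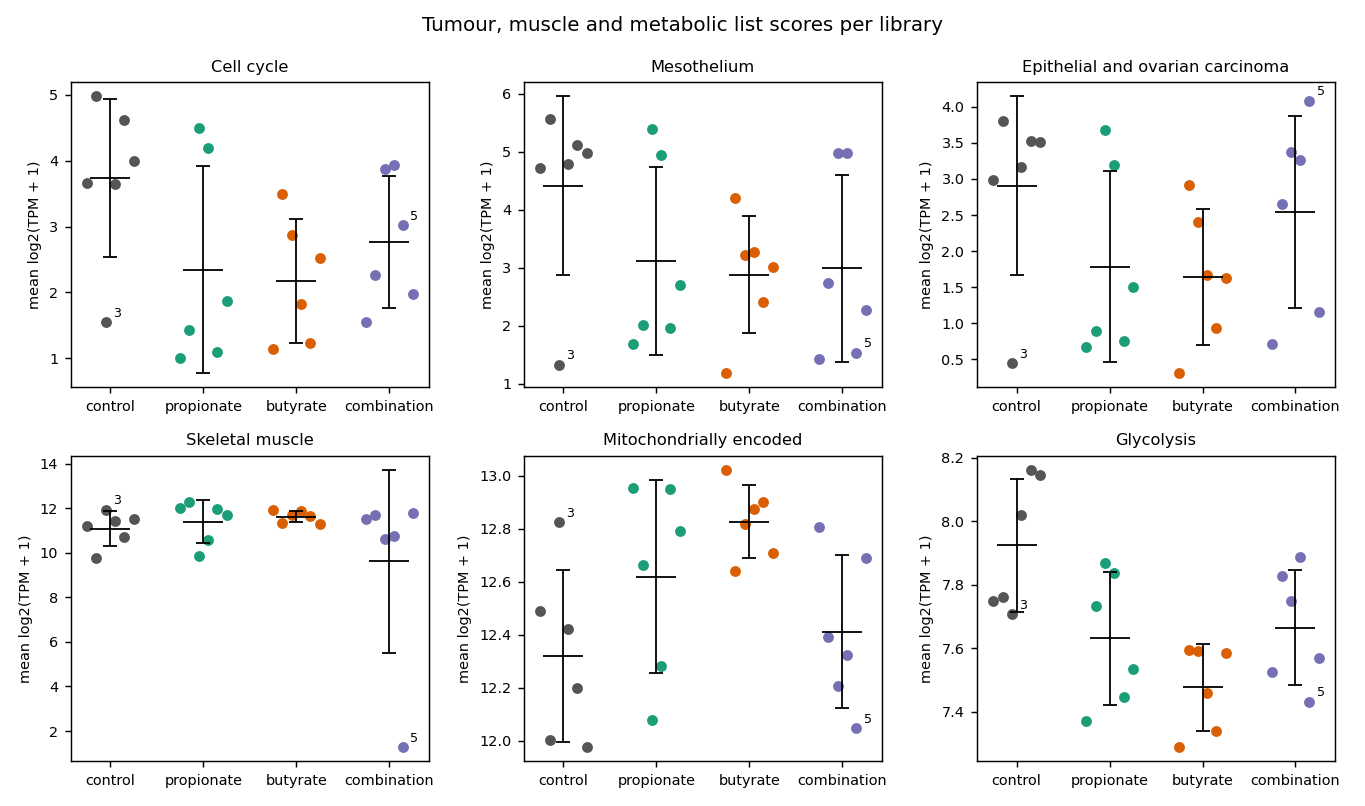
Tissue and cell cycle list scores by group. Points are libraries (6 per group) on an axis of mean log2(TPM + 1) over the members of a list, bars give the mean and SD, 5 marks combination replicate 5 and 3 marks control replicate 3; the cell cycle score averaged 3.74 in control and 2.35, 2.18 and 2.77 in the treated groups.

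Of 42 lists, camera called 18 higher and 4 lower in the combination group, 1 with an estimated correlation and 1 by fry, in both the neutrophil list. In limma 0 of 15163 genes passed, 940 were higher and 622 lower at an unadjusted p under 0.05, and the smallest adjusted p was 0.172. The 10 named genes, none past the threshold, were all above control. The matrix protein gene Dpt averaged 428 ± 74.5 TPM against 236 ± 34.4, a log2 fold change of 0.86 ± 0.16 with 36 of 36 pairs higher. Xdh, which makes uric acid, was at 0.85 ± 0.17, the stem cell antigen gene Ly6a at 0.85 ± 0.18 and the dipeptidase gene Dpep1 at 1.10 ± 0.23. Akr1c18, which breaks down progesterone, was at 1.80 ± 0.37, the phospholipase gene Pla2g2d at 2.14 ± 0.45, the lectin gene Cd209f at 1.35 ± 0.28 and the alcohol dehydrogenase gene Adh1 at 1.47 ± 0.31. Galnt15 was at 0.99 ± 0.21 and Rnf130 at 0.60 ± 0.13. With median-of-ratios scaling 35 genes passed, 35 higher and 0 lower, with quantile normalization 41 (40 and 1), and with tissue covariates 228 (226 and 2). Weights estimated per library gave 5786 (1018 and 4768), and leaving out combination replicate 6 gave 2.

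Receptors, checkpoint and effector genes were examined singly in the combination group. Ffar2 averaged 3.95 ± 4.44 TPM against 0.73 ± 0.30, a log2 fold change of 1.08 ± 0.36 (SE, n = 6 per group; limma, adjusted p = 0.300). Hcar2 averaged 3.39 ± 3.14 against 0.89 ± 0.20, at 0.95 ± 0.29 (adjusted p = 0.265). Cd274, which encodes PD-L1, averaged 11.5 ± 6.56 against 4.34 ± 1.5, at 1.08 ± 0.32 (adjusted p = 0.259). Gzmb averaged 2.09 ± 1.42 against 0.30 ± 0.26 (adjusted p = 0.202), and Cd8a 12.2 ± 27.0 against 0.64 ± 0.42 (adjusted p = 0.518). Combination replicate 5 held 67.3 TPM of Cd8a and the other 5 libraries 0.04 to 3.17, and it was also the highest of the 6 for Ffar2 (11.9 TPM), Hcar2 (8.47), Prf1 (5.98) and Foxp3 (5.29). Pdcd1, which encodes PD-1, averaged 1.20 ± 1.18 against 0.97 ± 0.56. Below the filter, and so not tested, were Prf1 at 1.39 ± 2.28 against 0.24 ± 0.17, Ifng at 0.96 ± 0.71 against 0.42 ± 0.18, Foxp3 at 1.34 ± 2.00 against 0.47 ± 0.24, and Ffar3, at 0.24 TPM or less in every library. Slc16a1 averaged 15.0 ± 4.56 TPM, at -0.56 ± 0.21 (adjusted p = 0.356), and the cell cycle inhibitor Cdkn1a 35.8 ± 6.96 against 45.2 ± 5.51 (adjusted p = 0.508). The list of SCFA and ketone body catabolism was called higher at a mean of 0.26 (adjusted p = 0.000598, but adjusted p = 0.532 with an estimated correlation), with the synthetase gene Acss3 at 1.14 ± 0.38. That mean was 0.09 without combination replicate 5, still called, and tissue covariates ended the call at -0.039.

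Combination against propionate asked what adding butyrate to propionate did. Type I interferon response genes were higher: all 18 lay above propionate, with a mean log2 fold change of 0.76 against a median of 0.19 over all genes (n = 6 per group). Rsad2 was at 0.77 ± 0.24 (SE), the antiviral synthetase gene Oas1a at 0.94 ± 0.30, Cmpk2 at 0.74 ± 0.24 and the interferon regulator Irf7 at 0.88 ± 0.29, and 12 genes rose when adjusted over the list alone, 0 over all genes. All 8 neutrophil genes lay above propionate, with a mean of 1.05, and 7 rose when adjusted over the list alone, S100a8 at 1.82 ± 0.65. All 16 macrophage genes lay above, with a mean of 0.646, and the mannose receptor gene Mrc1 at 0.78 ± 0.21. Camera called these lists higher (adjusted p = 4.83e-08, 6.60e-06 and 8.04e-05), but adjusted p = 0.511, 0.195 and 0.511 with an estimated correlation. Fry gave the neutrophil list an adjusted p of 0.0120. Class I presentation had a mean of 0.905, all 14 genes above, and inflammatory cytokines a mean of 0.69, all 13 above, with Il1b at 1.13 ± 0.46 and Ccl2 at 1.19 ± 0.50. Both were called (adjusted p = 2.30e-05 and 0.00372, but adjusted p = 0.511 and 0.525 with an estimated correlation).

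Muscle genes lay below propionate in the combination group, with all 16 lower, a mean of -1.79 and Ttn, which encodes titin, at -1.80 ± 0.80. Camera called the list lower (adjusted p = 3.98e-14, but adjusted p = 0.511 with an estimated correlation). Without combination replicate 5 that mean was -0.12, still called, and with tissue covariates it was 0.10, with no call. Camera called 16 lists higher and 7 lower, and 0 with an estimated correlation. In limma 0 of 15163 genes passed, 1278 were higher and 65 lower at an unadjusted p under 0.05, and the smallest adjusted p was 0.507. Among the named genes, none past the threshold, the lectin gene Cd302 was at 0.90 ± 0.20, Retnlg at 1.33 ± 0.30, Slfn5 at 0.95 ± 0.23 and Dapk1, a death-associated kinase, at 0.80 ± 0.19. Ifi207 of the interferon-inducible p200 family was at 0.84 ± 0.20, the sialic acid enzyme gene Npl at 0.82 ± 0.20 and Ly6a at 0.74 ± 0.18. Gapt was at 0.75 ± 0.18, Susd1 at 0.97 ± 0.24 and Rab27a, which acts in granule release, at 0.94 ± 0.23. With weights estimated per library, 5026 genes passed, 4818 higher and 208 lower.

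Combination against butyrate asked what adding propionate to butyrate did. Interferon gamma and class I presentation genes were higher: all 16 and all 14 lay above butyrate, with mean log2 fold changes of 1.29 and 1.28 against a median of 0.30 over all genes (n = 6 per group). When adjusted over the list alone, 14 and 13 of them rose, and 0 over all genes. Tgtp1 was at 1.67 ± 0.42 (SE), Gbp5 at 1.23 ± 0.32 and Irgm2 at 1.35 ± 0.43, and the immunoproteasome genes Psmb8 and Psmb10 at 1.58 ± 0.51 and 1.03 ± 0.27. Camera called both lists higher (adjusted p = 4.32e-07 and 3.08e-07), but adjusted p = 0.661 for both with an estimated correlation. All 16 tested T cell genes lay above butyrate, with a mean of 1.51, and all 8 tested cytotoxic genes, with a mean of 1.56. Of these, 14 and 8 rose when adjusted over the list alone, Cd3e at 1.90 ± 0.59 and Nkg7 at 1.92 ± 0.59. Both were called (adjusted p = 3.37e-06 and 2.31e-05, but adjusted p = 0.661 and 0.652 with an estimated correlation). The T cell mean was 0.82 without combination replicate 5, and both lists were called in each fit without 1 library.

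Class II presentation was called higher in this comparison, with all 11 genes above butyrate, a mean of 1.22 and the peptide loader H2-DMb2 at 1.71 ± 0.61 (adjusted p = 0.0158, but adjusted p = 0.734 with an estimated correlation). Mitochondrially encoded genes were called lower, all 11 below, with a mean of -0.42 and mt-Nd6 at -0.52 ± 0.15 (adjusted p = 7.97e-15, but adjusted p = 0.378 with an estimated correlation), and 2 of them fell when adjusted over the list alone. Skeletal muscle genes were called lower with them, all 16 below, at a mean of -2.02 (adjusted p = 3.44e-17, but adjusted p = 0.539 with an estimated correlation), which was -0.35 without combination replicate 5 and -0.44 with weights per library, still called, and 0.09 with tissue covariates, with no call. Camera called 13 lists higher and 5 lower, and 0 with an estimated correlation, while fry called 1 list, with an adjusted p of 0.0240. In limma 0 of 15163 genes passed, 2213 were higher and 141 lower at an unadjusted p under 0.05, and the smallest adjusted p was 0.317. Cd274 averaged 11.5 ± 6.56 TPM against 3.51 ± 0.52, a log2 fold change of 1.28 ± 0.32 that did not pass. None of the other named genes passed: the interferon-induced tryptophan tRNA synthetase gene Wars1 was at 0.72 ± 0.16, the adaptor gene Dok2 at 0.93 ± 0.21, the matrix gene Tgfbi at 0.52 ± 0.12 and the glutathione transferase gene Gstt1 at 0.84 ± 0.21. Nmral1 was at 0.70 ± 0.16, Gapt at 0.74 ± 0.18, Snrnp25 of the minor spliceosome at 0.59 ± 0.13 and Sys1 at 0.51 ± 0.12. Weights estimated per library gave 572 genes, 562 higher and 10 lower, a block by library number 5, and leaving out butyrate replicate 6 or combination replicate 6 gave 1.

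Butyrate against propionate compared the related acids directly, at doses that the labels do not give. Interferon gamma response genes were called lower with butyrate: all 16 lay below propionate, with a mean log2 fold change of -0.54 (n = 6 per group), Igtp at -0.87 ± 0.57 (SE), Irgm2 at -0.68 ± 0.43, Tgtp1 at -0.64 ± 0.42 and Gbp5 at -0.51 ± 0.32. Mitochondrially encoded genes were called higher, all 11 above, with a mean of 0.21, mt-Nd3 at 0.39 ± 0.28. Fibroblast and matrix genes were called higher too, 15 of 18 above, with a mean of 0.17, Fap, a marker of activated fibroblasts, at 0.34 ± 0.17. Adjusted p values were 6.51e-05, 1.98e-07 and 8.14e-06, but adjusted p = 0.982 for each with an estimated correlation, and 0 genes passed when adjusted over a list alone or over all genes. The interferon mean was -0.30 without propionate replicate 3 and -0.28 without propionate replicate 4, and with weights per library it turned to 0.23, with no call. Without propionate replicate 3 the mitochondrially encoded call ended at 0.10, as with quantile normalization (0.104) and with weights (-0.03), and without butyrate replicate 3 that of fibroblasts at -0.015. The fibroblast mean was 0.08 without propionate replicate 1 or 5 or butyrate replicate 2, 0.33 without propionate replicate 3 and 0.31 without butyrate replicate 1.

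In limma 0 of 15163 genes passed between the acids, 25 were higher and 82 lower at an unadjusted p under 0.05, and the smallest adjusted p was 1. The median 95% interval of a difference reached 0.551 log2 to either side, and for 11718 genes (77.3%) it lay within 1 log2 of 0, so smaller differences stay open. For Slc16a1 the interval ran from -0.70 to 0.15, for Ffar2 from -0.62 to 0.89, for Hcar2 from -0.55 to 0.64 and for Cd8a from -1.75 to 0.91. Named genes that did not pass included Cdk5rap1 at -0.41 ± 0.11, with 1 of 36 pairs higher, and the folate cycle genes Mtrr at -0.32 ± 0.12 and Shmt1 at -0.45 ± 0.17. Selenbp1 was at -0.41 ± 0.15, Med24 of the Mediator complex at -0.38 ± 0.13, Thap11 at -0.32 ± 0.11, Snrnp25 at -0.34 ± 0.13 and the translation initiation gene Eif2b5 at -0.25 ± 0.10. The pseudogenes Erhrt-ps at 1.57 ± 0.56 and Rpl27-ps3 at -1.24 ± 0.49 are uncertain, since they can share reads with their parent genes. Camera called 6 lists higher and 2 lower, and 0 with an estimated correlation or by fry. Weights estimated per library gave 0 genes, with 1397 at an unadjusted p under 0.05.

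The interaction asked whether butyrate differed in effect with and without propionate. Class I presentation and type I interferon genes had positive values: all 14 and all 18 were above 0, with mean interactions of 1.56 and 1.152 log2 against a median of 0.62 over all genes (n = 6 in each of 4 groups). Psmb8 was at 1.94 ± 0.72 (SE), the peptide transporter gene Tap2 at 1.49 ± 0.55, Oas1a at 1.38 ± 0.42 and Cmpk2 at 1.02 ± 0.34. When adjusted over the list alone, 12 and 10 genes passed, and 0 over all genes. Camera called both higher (adjusted p = 0.0156 and 0.0201), but adjusted p = 0.934 for both with an estimated correlation. Mitochondrially encoded genes were negative, all 11 below 0, with a mean of -0.72, mt-Nd3 at -1.15 ± 0.39 and 9 passing when adjusted over the list alone (camera adjusted p = 1.32e-18, but adjusted p = 0.160 with an estimated correlation). The type I interferon call ended without control replicate 1 (1.139), control replicate 3 (1.27), propionate replicate 4 (1.243), butyrate replicate 2 (1.199) or butyrate replicate 3 (1.151). With tissue covariates the calls of class I presentation and type I interferon ended at 0.65 and 0.565, and mitochondrially encoded genes were at -0.383, still called. Weights per library ended the type I interferon call at 1.38, and quantile normalization ended that of mitochondrially encoded genes at -0.29. The means of class I presentation, type I interferon and mitochondrially encoded genes were 0.88, 0.57 and -1.42 with median-of-ratios scaling, and the first 2 were 0.99 and 0.47 with quantile normalization, still called.

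No gene passed for the interaction in limma: 0 of 15163, with 5275 positive and 144 negative at an unadjusted p under 0.05 and a smallest adjusted p of 0.128. Scaling moved its median over all genes from 0.62 to 0.05 by median-of-ratios and to -0.01 by quantiles. The named genes, none past the threshold, were positive: Pxdc1 at 1.85 ± 0.44, the cell cycle repressor E2f4 at 0.75 ± 0.18, the mitochondrial carrier gene Slc25a25 at 1.48 ± 0.36 and Cad, which starts pyrimidine synthesis, at 1.33 ± 0.34. The transcription factor gene Cebpb was at 0.76 ± 0.19, the coenzyme A synthesis gene Ppcdc at 1.44 ± 0.36, the G protein gene Gna11 at 0.81 ± 0.21 and Mrpl17 of the mitochondrial ribosome at 0.85 ± 0.22. Ddx49 was at 0.89 ± 0.22 and Psmd9 at 0.81 ± 0.20. Camera called 2 lists higher and 6 lower, and 0 with an estimated correlation or by fry. Weights estimated per library gave 10982 genes, a block by library number 5426, and leaving out propionate replicate 3 gave 5619, 5512 positive and 107 negative.

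The 3 comparisons with control share their control libraries, so their fold changes are correlated even with no effect. Across the 15163 genes, which are not independent replicates, propionate and butyrate changes had r = 0.921 and a covariance of 0.216. Simulations of unchanged groups shuffled the residuals of all 24 libraries and kept a control group shared by both comparisons. They gave a median r of 0.587 and a mean covariance of 0.062. Of 100 simulations, 2 had a covariance as large and 0 an r as large. With the controls split between both comparisons, the median r was 0.680 and the mean covariance 0.165. For propionate and the combination r was 0.669 and the covariance 0.144, against 0.586 and 0.058 simulated and 0.458 and 0.093 with split controls. For butyrate and the combination r was 0.632 and the covariance 0.164, against 0.460 and 0.053 simulated and 0.480 and 0.113 with split controls. For the last 2 pairs, 8 and 7 of 100 simulations had a covariance as large, and 34 and 33 an r as large.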

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

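The tissue covariates, leaving out each library and the scalings were planned settings, but their use as tests of the patterns in this part, and all other tests here, were chosen only after the result was seen, except median-of-ratios scaling for the cell cycle list. In 216 sets of 6 values, 24 had a library far from the other 5 by Dixon's test. Chance flags about 1 in 20 groups, or 10.8 here. Of the 24, 6 were in combination replicate 5.

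Combination replicate 5 had a T cell score of 5.961, a B cell score of 6.505, a skeletal muscle score of 1.28 and 67.3 TPM of Cd8a, each far from the other 5 combination libraries. Its SCFA and ketone body catabolism score of 5.47 and its intestinal epithelium score of 3.83 also lay apart. A degraded or shallow library stays open. Its 15418 genes with a TPM of at least 1 were the most of the 24 libraries, but its skeletal muscle genes took 0.00702% of the TPM, which raises the TPM of all other genes, and the depth is unknown. Of 37 tested members of the B cell, T cell and adipocyte lists, 36 had their highest TPM in it, but for B and T cells this restates the scores that set it apart and tests nothing. Fat in the piece is consistent with 13 of 14 adipocyte genes being highest in it, a list whose score did not lie apart, and lymphoid tissue stays open. Whether the treatment brought this tissue cannot be told apart from what the sampled piece held. Of the 5 other combination libraries, 4 correlated with it above the control median of 0.745, but so did propionate replicates 3 (0.7901, the highest of any library) and 4 (0.7762) and butyrate replicates 2 and 6. A single piece of this kind was seen, and the labels do not describe the sampling.

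Of 17 immune lists, 13 were called higher in the combination group than in control, and with an estimated correlation only the neutrophil list passed. When combination replicate 5 was left out, 11 of the 13 stayed called, and for the B cell and regulatory T cell lists 0 of 2, at 0.073 and 0.126 after 0.955 and 0.373. It is argued against as the whole cause for the neutrophil, cytotoxic, interferon gamma and alternative macrophage lists, whose means went from 1.145, 1.341, 0.601 and 0.422 to 0.946, 0.933, 0.532 and 0.386. The T cell, checkpoint, resident macrophage and dendritic cell means went from 1.199, 0.399, 0.333 and 0.373 to 0.505, 0.166, 0.115 and 0.072, that of type I interferon from 0.393 to 0.238, and that of class I presentation, 0.63 with it, was 0.38. For these 6 lists, much of the difference may rest on that library, though each stayed called. The macrophage list, also still called, had a mean of only 0.08 with all libraries. Its call ended without control replicate 3 or combination replicate 3. With the tissue covariates 12 of the 13 stayed called, all but the B cell list. Other splits of the combination and control libraries, fitted without covariates, called a median of 16 lists. Staying called is thus too easy to decide whether muscle, fat and other tissue in the piece were the whole cause. The splits of the samples did not test the immune lists by themselves. A response to the combination remains a hypothesis, and differences in lymphoid tissue between pieces that these covariates do not capture may also contribute.

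The cell cycle list was called lower in each of the 3 treated groups than in control, but in none with an estimated correlation (adjusted p = 0.787, 0.968 and 0.623). A larger TPM share of muscle and mitochondrial transcripts is argued against as the whole cause, since at least 77.9% of the mean log2 fold change was kept with median-of-ratios scaling. A smaller share of tumour or mesothelium in the piece stays open. Mki67 did run with Wt1 over the libraries. It was at 7.47 TPM or more where Wt1 was at 131 TPM or more. Where Wt1 was at 28.0 TPM or less, Mki67 was at 2.69 TPM or less, except in combination replicate 5 (4.91 TPM). These are single genes, and they do not decide the cause. The tissue covariates come from lists of other tissues, with no list of tumour or mesothelium among them, so they cannot decide it. With them at most 20.9% was kept, and the call ended for butyrate and the combination. Much of the difference thus went with the other tissues measured. The means moved from -1.39 to -0.29 with propionate, from -1.56 to -0.24 with butyrate and from -0.97 to 0.17 with the combination. Epithelial and ovarian carcinoma genes, a more direct measure of tumour, scored 2.908 in control and 1.783, 1.642 and 2.542 with propionate, butyrate and the combination (exact permutation p = 0.197, 0.0758 and 0.682). None passed, and in the combination the mean score differed little from control. Its libraries ran from 0.717 to 4.085, against 0.45 to 3.807 in control. Combination replicate 5 held 123 TPM of Krt8 of that list, but 0 TPM of Wt1 and 0.49 of Msln, both mesothelium genes. The score therefore leaves a smaller tumour share open there too. A smaller tumour share could itself be an effect of treatment, which stays open, as covariates that follow it would remove it too.

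Control replicate 3 lay apart from the other 5 controls in 12 list scores and in its number of genes. Its scores were 1.246 for checkpoint genes, 0.47 for B cells, 1.60 for dendritic cells, 1.89 for mast cells and eosinophils, 4.95 for class I and 4.51 for class II presentation, and 1.61 for inflammatory cytokines. It also scored 0.45 for epithelial and ovarian carcinoma genes, 1.33 for mesothelium, 3.91 for lipid and sterol synthesis, 0.418 for exocrine pancreas and 0.509 for ovary, with 13131 genes at a TPM of at least 1. Control replicate 5 had an immediate early score of 5.01 and 0.79 TPM of Gzmb. Control replicate 2 had a smooth muscle score of 4.24. Combination replicate 2 had a score of 4.03 for SCFA receptors and transporters. Butyrate replicate 6 had 2.25 TPM of Hcar2.

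Camera compares a list with all other genes, whose median interaction was 0.62, and it called 8 lists as differing from them. The lower calls of oxidative phosphorylation, fatty acid oxidation and smooth muscle genes therefore show mainly that these lists did not follow that shift. The mean interactions were 1.152 for type I interferon, 1.56 for class I presentation, -0.15 for oxidative phosphorylation, -0.009 for fatty acid oxidation and -0.72 for mitochondrially encoded genes. Those of skeletal muscle, smooth muscle and erythroid genes were -2.325, -0.106 and -0.31, and 0 of the 8 calls held with an estimated correlation (smallest adjusted p = 0.160). Their size depended on scaling: median-of-ratios gave 0.88, 0.57, -0.854, -0.692, -1.423, -0.745 and -0.98 for class I presentation, type I interferon, oxidative phosphorylation, fatty acid oxidation, mitochondrially encoded, smooth muscle and erythroid genes. Quantile normalization gave 0.99, 0.47, -0.55 and -0.53 for the first 4, and ended the calls of the last 3 at -0.29, -0.715 and -0.82. Without combination replicate 5 the skeletal muscle value was -0.66 and that of oxidative phosphorylation -0.075, which was -0.09 without control replicate 2, -0.07 without propionate replicate 2 and -0.23 without propionate replicate 3. The erythroid call ended without control replicate 4, at -0.03. Its value was -0.15, -0.105, -0.16 and -0.095 without propionate replicate 3, butyrate replicates 2 and 6 and combination replicate 4, -0.57 without butyrate replicate 1, and -0.53 without control replicate 6 and without combination replicate 6. The smooth muscle value ran from -0.21 without combination replicate 2 to -0.005 without control replicate 2, and that of fatty acid oxidation from -0.07 without control replicate 3 to 0.09 without propionate replicate 2. Tissue covariates ended every call but that of mitochondrially encoded genes, at -0.383. For skeletal muscle, smooth muscle and erythroid genes this tests nothing, since their lists helped to make the covariates. The values then were 0.115 for skeletal muscle, 0.149 for oxidative phosphorylation, 0.123 for fatty acid oxidation, 0.113 for smooth muscle and -0.202 for erythroid genes. Those of class I presentation and type I interferon were 0.651 and 0.565.

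Splits of the libraries into other groups of the same size were refitted, 100 for each comparison with the real one. In limma the real split called 0 genes in each of the 7 comparisons. Any split calls at least 0, so that 100 of 100 called as many was fixed beforehand and tests nothing. The other splits called up to 9358 genes for propionate against control, 1 for butyrate, 4109 for the combination, 11042 for combination against propionate, 34 for combination against butyrate, 7379 for butyrate against propionate and 1 for the interaction. Splits that call so many genes point to a structure of the samples other than the groups. Libraries parted by Wt1 of the mesothelium list and Krt8 of the carcinoma list along the first principal component, but whether this made the calls was not tested.

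By the count at an unadjusted p under 0.05, few splits did as well for butyrate against control (5506 genes, 3 of 100 splits, highest other 7314) and for the interaction (5419, 3 of 100, 7842). Chance is not firmly excluded for these either, since 21 counts of genes and lists were judged without adjustment, and with median-of-ratios scaling the medians of all genes went from -0.38 to -0.01 and from 0.62 to 0.05. It could not be excluded for propionate (1451, 13 of 100, 10039), the combination (1562, 10 of 100, 8201) or combination against propionate (1343, 25 of 100, 11359). Nor could it be for combination against butyrate (2354, 5 of 100, 5585) or butyrate against propionate (107, 59 of 100, 8785). By the number of lists called, chance could be excluded for none of the 7. The counts were 14 for propionate (18 of 100, highest other 23), 10 for butyrate (62 of 100, 21), 22 for the combination (14 of 100, 25) and 23 for combination against propionate (5 of 100, 26). They were 18 for combination against butyrate (33 of 100, 24), 8 for butyrate against propionate (77 of 100, 20) and 8 for the interaction (94 of 100, 25).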

How the results depend on the processing

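Fits of all groups without combination replicate 5, alone or with covariates, were the tests chosen after the data were seen, and all other settings were planned. Of 103 list calls, 7 turned direction with weights per library and 12 with tissue covariates, and 37 ended with these covariates, 27 with weights, 26 with quantile normalization, 21 without a filter and 19 with median-of-ratios scaling. A block by library number ended 14, a filter of TPM at least 5 ended 9, a fit of the compared groups 5, a pseudocount of 0.1 ended 5, a block by title number 1 and moderation without trend and robustness 0. Fewer than 103 calls could be scored with that filter and with the fit of the compared groups, where 91 and 90 stayed. With 6 libraries per group and an unknown depth, small changes of low genes stay open. The counts with tissue covariates include lists that helped to make them, such as adipocyte and skeletal muscle. For those lists the outcome was largely fixed beforehand. The cause was not tested for any of these changes.

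In limma, median-of-ratios scaling called 35 genes for the combination (35 higher, 0 lower), with 5 lists for butyrate against propionate and 24 for the interaction. Quantile normalization called 41 genes for the combination (40 and 1), with 9 lists for propionate and 19 for the interaction. Without a filter 4 lists were called for butyrate against propionate and 20 for the interaction. With an estimated correlation the lists called were 0 for propionate, 0 for butyrate, 1 for the combination, and 0 in the other 4 comparisons.

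Weights per library called 11434 genes for propionate, 10256 for butyrate, 5786 for the combination, 5026 for combination against propionate, 572 for combination against butyrate and 10982 for the interaction, and 14 lists for butyrate against propionate. The lowest of these weights were 0.126 for combination replicate 5, 0.127 and 0.181 for propionate replicates 3 and 4 and 0.26 for control replicate 3. With propionate Cd8a turned (-0.56), and camera's direction turned for the interferon gamma list (-1.115), whose mean was already -0.153 without weights. In the combination it turned for skeletal muscle (0.13). Between butyrate and propionate it turned for interferon gamma (0.23), class I presentation (0.26), mitochondrially encoded genes (-0.027), skeletal muscle (-0.19) and endothelium (0.014), whose mean stayed above 0.

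With tissue covariates 228 genes were called for the combination (226 and 2), 18 lists for butyrate and 2 for the interaction. Camera's direction turned for oxidative phosphorylation (mean -0.105), fatty acid oxidation (-0.067) and smooth muscle (-0.128) with propionate, and with butyrate (-0.154, -0.209 and -0.175), where the mean of fatty acid oxidation was already -0.058 without covariates. In the combination it turned for SCFA catabolism (-0.039), cell cycle (0.167), mesothelium (0.351), skeletal muscle (0.076) and ovary (0.339), and against propionate for skeletal muscle (0.103).

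With these covariates and without combination replicate 5, 38 genes were called for the combination, 18 lists for butyrate and 5 for the interaction. Means were -0.089 for oxidative phosphorylation, -0.151 for adipocytes and -0.108 for smooth muscle with propionate, and -0.147, -0.201 and -0.167 for oxidative phosphorylation, fatty acid oxidation and smooth muscle with butyrate. In the combination SCFA catabolism was at -0.039, adipocytes at 0.071 and skeletal muscle at 0.027, and skeletal muscle was at 0.077 against propionate. Oxidative phosphorylation was at 0.161 in the interaction.

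With components of the other 23 libraries instead, 760 genes were called for butyrate (27 and 733), 12 for the combination and 11 for the interaction, and 16 lists for butyrate and 4 for the interaction. Means were -0.105 for oxidative phosphorylation, -0.159 for skeletal muscle and -0.14 for smooth muscle with propionate, and -0.153, -0.201 and -0.196 for oxidative phosphorylation, fatty acid oxidation and smooth muscle with butyrate. In the combination SCFA catabolism was at -0.047, endothelium at 0.013 (called the other way) and erythroid genes at -0.081, adipocytes were at 0.136 against propionate, and oxidative phosphorylation was at 0.154 in the interaction.

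Whether replicate numbers pair the samples stays open. Deviations of libraries with the same title number correlated above 0.1 in 16 of 36 pairs (median -0.073, against -0.021 for other pairs), and with the same library number in 18 of 27 (0.239 against -0.059), among them all 4 pairs of propionate and combination (0.68, 0.596, 0.239 and 0.632). Of 24 libraries, 3 and 2 correlated best with their own number. A replicate block by title number called 0 genes in all 7 comparisons, and 13 lists for propionate, 11 for butyrate, 23 for the combination, 23 and 18 for the combination against each acid, 8 for butyrate against propionate and 9 for the interaction. A block by library number called 7903 genes for butyrate (181 and 7722), 5 for combination against butyrate and 5426 for the interaction (5383 and 43), and 13 lists for butyrate against propionate. For combination against propionate it called 0 genes and 18 lists instead of 23.

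Leaving out 1 library at a time gave 0 genes for propionate, 0 to 5654 for butyrate (without control replicate 3), 0 to 2 for the combination (without combination replicate 6), 0 for combination against propionate, 0 to 1 for combination against butyrate (without butyrate replicate 6 or combination replicate 6), 0 for butyrate against propionate and 0 to 5619 for the interaction (without propionate replicate 3). Lists called ran from 12 to 16 for propionate, 8 to 12 for butyrate, 20 to 25 for the combination, 20 to 25 and 16 to 23 for the combination against propionate and butyrate, 6 to 11 for butyrate against propionate and 7 to 12 for the interaction.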

Other observations

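The splits of the samples in this part were tested only after the results were seen, and the 5 settings they were run on were picked, out of 14, because those settings called genes. The fits without combination replicate 5 were also chosen after the data were seen.

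Scores of sugar metabolism and hypoxia genes were below control in the butyrate group, but did not pass adjustment and had means near 0 with median-of-ratios scaling. The glycolysis score was 7.48 ± 0.14 against 7.92 ± 0.21 in control (SD, n = 6 per group), lower in all 36 pairs, with an exact permutation p = 0.00216, the smallest the test can give, and an adjusted p of 0.273 over 126 tests. Eno1, an enolase, was at -1.26 ± 0.39 (SE), the hexokinase gene Hk1 at -1.32 ± 0.48 and the glucose carrier gene Slc2a1 at -0.75 ± 0.29, and 6 of 15 genes fell when adjusted over the list alone, 0 over all genes. The list's mean was -0.45 and its median -0.15, while camera placed it above the other genes and did not call it (adjusted p = 0.660), and with median-of-ratios scaling its mean was -0.01. Hypoxia genes scored 4.25 ± 0.16 against 4.68 ± 0.25 (exact permutation p = 0.00866, adjusted p = 0.273, 3 of 36 pairs higher), with P4ha1, which modifies collagen, at -0.70 ± 0.21. Their mean of -0.43 was 0.001 with quantile normalization, and camera did not call them.

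Among histone deacetylases, many of which butyrate inhibits, 13 of 14 genes were below control with butyrate, with a mean log2 fold change of -0.49 (n = 6 per group). Hdac5 was at -0.49 ± 0.14 (SE) and Hdac3 at -0.57 ± 0.21, 1 gene fell when adjusted over the list alone and 0 over all genes, and the list was not called (camera adjusted p = 0.289). Its mean was -0.091 with median-of-ratios scaling. Immediate early genes, which also respond to tissue handling, scored 3.26 ± 0.62 against 4.03 ± 0.48 (exact permutation p = 0.0346, adjusted p = 0.225 over 39 tests, 5 of 36 pairs higher), with Jun at -0.84 ± 0.21, Fosb at -1.18 ± 0.36 and Fos at -1.46 ± 0.51.

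With tissue covariates, 228 genes passed between the combination and control, 226 higher and 2 lower, against 0 without them. They included 5 of 8 tested cytotoxic genes (Nkg7 at 1.70 ± 0.43, Klrd1 at 1.17 ± 0.28) and 4 of 16 tested T cell genes (Cd3e at 1.33 ± 0.29). They also held 4 of 12 dendritic cell genes, among them Clec9a and Xcr1 of cross-presenting cells at 1.04 ± 0.23 and 0.69 ± 0.17. Also among them were 5 of 16 macrophage genes (the complement gene C1qa at 0.82 ± 0.21), 5 of 11 class II genes (H2-Aa at 1.12 ± 0.27), and the leukocyte genes Ptpn22 at 1.28 ± 0.21 and Cd40 at 1.03 ± 0.19. Of the 228, 21 also passed with median-of-ratios scaling and 25 with quantile normalization. Without combination replicate 5, and with the same covariates, 38 of them passed, and 11 with components of the other 23 libraries. All 228 had the same sign without that library, with a median log2 fold change of 0.80 against 0.87. They were picked by passing in a fit that shares the other 23 libraries, so like signs and sizes were largely built in and test nothing.

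For these 228 genes, the highest of the other splits called 1 gene, and 1 of 100, the real one, called as many. With median-of-ratios scaling 35 genes passed (1 of 100, highest other 1), with quantile normalization 41 (1 of 100, highest other 0), and for butyrate with a block by library number 7903 (1 of 100, highest other 7268). These splits do not exclude chance, because the settings were picked for calling genes in the real split and 1 of 100 is the smallest share the test can give. For propionate with weights per library, chance could not be excluded either: 11434 genes passed, 16 of 100 splits called as many and the highest other 12224, and 49 of the 100 weight estimates stopped before reaching their tolerance.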
